A study of Homo sapiens with 4 samples.

How the data were processed

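RNA-seq was performed on 4 libraries labelled as Huh7, a line derived from a human liver cancer. 2 libraries came from cells carrying a short hairpin RNA against NME7 (shNME7) and 2 from cells carrying a control hairpin (shCtrl). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were prepared by standard Illumina protocols. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom over recovered fragments lay between 14.0 and 44.1 for the 6 pairs of libraries.

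The authors deposited 1 table per library with an FPKM value (fragments scaled to gene length and library size) for each of 58735 genes, the unit being named in the file headers. Per the submitters' processing notes, HISAT2 2.0.5 was used and the genome build is listed as hg18. The counting tool, the annotation and any filter are not given in the sources used here. All 58735 gene IDs occur in GENCODE release 29 (Ensembl release 94), which annotates GRCh38 and not hg18. That release gave gene names and the exon lengths used below, and coordinates are from it, on GRCh38.

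Multiplying each deposited FPKM value by the gene's summed exon length gave whole multiples of a single step per library. For every gene above 0 (100% in each library) the result lay within 0.01 of a whole number, so the fragments behind each value were recovered. The recovered totals were 15865321 and 16050268 fragments for shCtrl 1 and 2, and 14877906 and 16991397 for shNME7 1 and 2. The totals implied by the steps equalled the median-ratio size factors of these fragments times the geometric mean of the library totals. This scaling is inferred from the values and is stated in no label. A count of 0 allows up to 3 fragments per library, or 0.177 to 0.202 CPM. This floor and the intervals given cover counting error only, since PCR copies cannot be told apart.

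The main test for genes was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), with a term for the group and no covariate, for the 12866 genes with a mean FPKM of at least 1 over the 4 libraries. Fold changes on this scale understate the change of low genes. P-values are two-sided and were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The plan had foreseen a count test had the files held counts; with FPKM, the test planned for normalized values was used.

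Gene lists were fixed before the data were examined: 34 lists with 713 members, all matched to an ID through GENCODE names or RefSeq synonyms. The 29 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. Members were also adjusted over the list alone. That adjustment does not correct for the number of lists, so single members can pass it by chance. Other lists are given as levels only. The lists include mitochondrially encoded genes, ribosomal proteins, replication-dependent histones and markers of fibroblasts, leukocytes and endothelium.

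The rule for named genes was also set before the data were examined. It takes NME7, MTHFD2, CTNNB1, MYC and CCND1 whatever their result, and the 12 genes per direction with the largest changes past the threshold. With fewer than 5 past it, the 10 genes with the smallest unadjusted p replace them. For each list it takes up to 4 members past the threshold, or otherwise up to 2 with the largest absolute change and a mean of at least 5 FPKM in the higher group. The 6 genes with the smallest adjusted p not named by these parts are given in the closing observations. Other genes named here were chosen after their values were seen. Some list members are not reported here by name.

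The alternatives planned in advance were a pseudocount of 0.1, no filter on low values, the replicate number as a block, each library left out in turn, stricter thresholds, camera with an estimated correlation, camera on ranks, and fry. Alternatives added after seeing the data were limma-voom on recovered fragments (15112 genes with a mean of at least 10 fragments), removal of a loess trend on GC content and exon length from each library (span 0.3), both together, protein-coding genes only, and a crossed pairing. GC values were available for 12857 of the 12866 tested genes.

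The tests were tested on simulated data with the fragment totals of these libraries and 200 changed genes, all with a mean of at least 100 fragments. Noise was drawn independently for each gene and library, with no GC trend, so recovery in the real data can be lower. Over the tested genes, the 2 real libraries of a group differed with an SD of 0.32 (shCtrl) and 0.36 (shNME7) in log2, counting error included. Pairs across the groups ran from 0.32 (shCtrl 2 with shNME7 1) to 0.44 (shCtrl 2 with shNME7 2), so replicates were not always the closest libraries. These are SDs of a difference between 2 libraries, whereas the simulated spreads apply to each library. At a spread of 0.1 on the log2 scale, limma-trend recovered 89% of the genes changed 2-fold and 98% of those changed 4-fold. At a spread of 0.2 it recovered 59% and 97%. limma-voom recovered 100% and 100% at the smaller spread, and 89% and 100% at the larger. False calls numbered 14 and 18 in limma-trend and 11 and 3 in limma-voom. Of 1000 random lists, camera gave an unadjusted p under 0.05 for 1.9% at the smaller spread and 1.6% at the larger. Members of these lists varied independently, so this rate does not cover lists whose members vary together. With the real libraries split across the groups in the 2 other ways, camera called 3 and 2 of the 29 lists. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.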

Results

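Transcript levels were measured by RNA-seq in 4 libraries labelled Huh7, 2 from cells with a control hairpin and 2 from cells with a hairpin against NME7. NME7 encodes a member of the nucleoside diphosphate kinase family that is found at the gamma-tubulin ring complex of centrosomes. Each library held between 14877906 and 16991397 recovered fragments, and 12854 to 13081 genes reached 1 FPKM. The mitochondrial share of fragments was 4.76% and 5.92% in shCtrl 1 and 2, and 6.59% and 4.24% in shNME7 1 and 2, and so overlapped between the groups. Libraries differed in their dependence on GC content, and over the tested genes the difference between shNME7 and shCtrl correlated with GC content (Spearman rho 0.41 across genes, which are not independent replicates). Values below are FPKM means ± SD with n = 2 per group unless stated otherwise.

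The comparison asked what changes in the transcriptome when NME7 is knocked down. The targeted gene itself was lower in both shNME7 libraries. NME7 (ENSG00000143156, chromosome 1, 169132531 to 169367967 on the minus strand of GRCh38) stood at 3.64 and 3.93 FPKM in shCtrl 1 and 2 and at 0.835 and 0.626 in shNME7 1 and 2. The means were 3.79 ± 0.210 and 0.731 ± 0.148, a level 5.18-fold lower, and the recovered fragments numbered 332 and 364 against 72 and 61. On the log2(FPKM + 1) scale the difference was -1.47 (SE 0.17), with an adjusted p of 0.310 in limma-trend, which did not pass. limma-voom on recovered fragments, a test added after seeing the data, gave -2.39 (SE 0.26) with an adjusted p of 0.000998. With any 1 library left out NME7 stayed lower, with values between -1.56 and -1.38 in limma-trend and between -2.59 and -2.17 in limma-voom.

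Beyond NME7, the lower genes that passed in limma-voom included the chromatin architectural protein gene HMGA1, the cystine transporter gene SLC7A11, the glutathione-degrading enzyme gene CHAC1, the stress pseudokinase gene TRIB3 and the ferritin light chain gene FTL. HMGA1 stood at 303 ± 55.9 FPKM in shCtrl and 101 ± 12.8 in shNME7, 3.02-fold lower. FTL stood at 922 ± 101 and 476 ± 24.7 FPKM, and the activin beta chain gene INHBE at 11.6 ± 3.01 and 3.59 ± 0.984. The butyrylcholinesterase gene BCHE was 3.42-fold lower, at 5.38 ± 1.09 against 1.57 ± 0.0930 FPKM, and the zinc finger transcription factor gene PLAG1 was 3.63-fold lower, at 2.30 ± 0.344 against 0.632 ± 0.0546. limma-trend, the main test, called 0 of 12866 genes, with 859 genes at an unadjusted p under 0.05 (445 higher and 414 lower) where 643 were expected by chance, and a smallest adjusted p of 0.310. limma-voom called 16 of 15112 genes, 2 higher and 14 lower, with 1197 genes at an unadjusted p under 0.05. Of all tested genes, 18.4% had both shNME7 libraries below both shCtrl libraries and 17.8% had both above, where chance gives 16.7% each way.

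The 14 genes that fell in limma-voom were HMGA1, NME7, SLC7A11, PLAG1, CHAC1, TRIB3, INHBE, BCHE, the long non-coding RNA AL713998.1, TRIM2, FTL, STC2, FLRT3 and the tight junction gene CLDN1. Their log2 differences in limma-voom ran from -2.39 for NME7 to -0.95 for FTL. The adjusted p was 0.000998 for HMGA1, 0.00505 for SLC7A11 and 0.00839 for CHAC1 and TRIB3. The 2 higher genes, the splicing factor gene U2AF1 and the cystathionine beta-synthase-like gene CBSL on chromosome 21, are uncertain because near-identical copies share their reads. Fragments of U2AF1 and its copy U2AF1L5 together numbered 111 and 153 in shCtrl and 416 and 349 in shNME7. Those of CBS and CBSL together, 822 and 321 against 701 and 597, overlapped between the groups. With the GC and length trend removed, limma-voom no longer called CHAC1, INHBE, TRIM2, STC2, FLRT3 or CBSL. The number of limma-trend calls, 0 with all libraries, rose whichever of shCtrl 1, shCtrl 2, shNME7 1 and shNME7 2 was left out. The lone library of a group was then assumed to vary like the other group, so the rise does not show that single libraries carry calls. limma-voom called 39, 28, 430 and 41 genes in the same order, and kept 14, 13, 16 and 16 of its 16 calls, those lost being FTL and STC2 without shCtrl 1 (adjusted p 0.146 and 0.127) and TRIM2, FLRT3 and CLDN1 without shCtrl 2 (0.0513, 0.186 and 0.136).

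**Figure D1:**
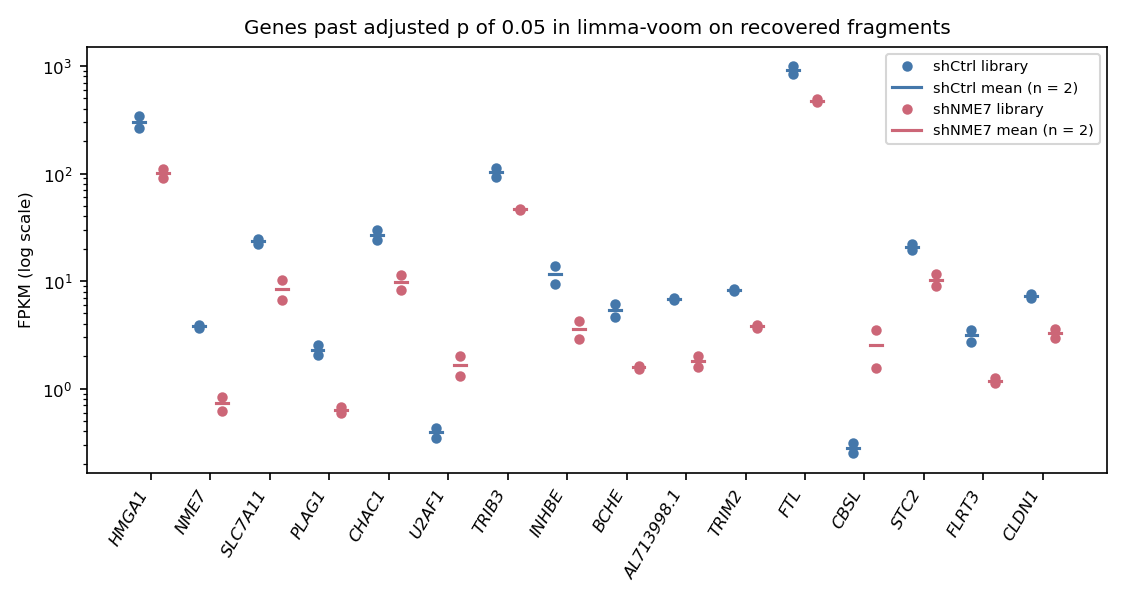
FPKM on a log axis of the 16 genes past an adjusted p of 0.05 in limma-voom on recovered fragments, 1 point per library and a bar at each group mean (n = 2). Both shNME7 libraries lie below both shCtrl libraries for 14 genes, among them NME7 (means 3.79 and 0.731), and above them for U2AF1 and CBSL, whose reads are shared with near-identical copies.

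With fewer than 5 genes past the threshold in limma-trend, the 10 with the smallest unadjusted p were taken, none of which passed. AL713998.1, NME7, HMGA1, BCHE and TRIB3 were the lower genes among them with over 30 fragments in each library. AL713998.1 stood at 6.84 ± 0.154 FPKM in shCtrl and 1.80 ± 0.313 in shNME7, and TRIB3 at 103 ± 15.2 and 46.3 ± 1.06. The other 5 were short RNA genes with 0 to 6 fragments per library, for which no fold is given. RNU7-20P, MIR339, RNA5SP474 and MIR6797 had 0 fragments in both shCtrl libraries and 2 to 6 in each shNME7 library, and RNU7-80P had 2 and 4 in shCtrl and 0 in both shNME7 libraries. Such counts lie near the limit of 3 fragments that a count of 0 allows.

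Genes of one-carbon metabolism and of Wnt signalling were fixed in advance. MTHFD2, the mitochondrial enzyme of folate metabolism, stood at 75.2 ± 4.34 FPKM in shCtrl and 51.6 ± 8.36 in shNME7, a log2 difference of -0.54 that did not pass (limma-trend adjusted p 0.728). Without shNME7 1 the difference was -0.71, and over its 11 alternatives it ran from -0.71 to -0.38. CTNNB1, which encodes beta-catenin, stood at 24.5 ± 0.383 and 22.9 ± 1.45 FPKM, a log2 difference of -0.09 whose sign flipped with the GC and length trend removed, to 0.02 in limma-trend and 0.04 in limma-voom. MYC stood at 249 ± 23.4 and 234 ± 2.11 FPKM, a log2 difference of -0.09 that became 0.01 without shCtrl 1. CCND1, the cyclin D1 gene, stood at 22.8 ± 2.56 and 18.4 ± 2.10 FPKM. None of the 4 passed in limma-trend or limma-voom with all libraries.

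Of the Wnt/beta-catenin target genes, 10 of 22 were tested, 2 of them higher and 8 lower in shNME7. The list was not called by camera (mean log2 difference -0.09, adjusted p 0.265). It was called lower in 1 of 11 alternatives, limma-voom with the GC and length trend removed (mean -0.22, adjusted p 0.0483, range 0.0483 to 0.647). TCF7L2 stood at 5.23 ± 0.173 FPKM in shCtrl and 3.56 ± 0.498 in shNME7, and GLUL at 3.99 ± 0.229 and 5.22 ± 0.390. Of the one-carbon and serine metabolism genes, 19 of 27 were tested, 6 higher and 13 lower, and the list was called lower (mean -0.14, median -0.03, camera adjusted p 0.0324). That call was lost with the correlation estimated from the data (adjusted p = 0.469 with an estimated correlation). The estimate was 0.0024, below the preset 0.01, so a higher correlation among members does not account for the loss. Adjusted over the list alone, 2 members fell, the serine synthesis genes PSAT1, at 190 ± 4.32 against 111 ± 12.5 FPKM, and PSPH, at 54.7 ± 4.68 against 33.1 ± 2.59. The call was lost in 7 of 11 alternatives. Besides the replicate block, these were no filter on low values (mean -0.11), the GC and length trend removed in limma-trend (-0.13) and in limma-voom (-0.12), and leaving out shCtrl 1 (-0.10), shNME7 1 (-0.17) or shNME7 2 (-0.12), and the adjusted p ran from 0.0152 to 0.260 over 11 alternatives.

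The most uniform group was the ATF4 amino acid response, genes that the transcription factor ATF4 induces when amino acids are scarce or protein folding is stressed. All 23 tested members had a lower mean in shNME7, and for 22 of them both shNME7 libraries lay below both shCtrl libraries, the exception being CTH. The mean log2 difference was -0.63 (SD 0.32 over members), and camera called the list with an adjusted p of 1.63e-20. That call was lost when the correlation was estimated (adjusted p = 0.469 with an estimated correlation). SLC7A11 stood at 23.5 ± 1.87 FPKM in shCtrl and 8.44 ± 2.44 in shNME7, and CHAC1 at 26.8 ± 3.88 and 9.87 ± 2.27. Adjusted over the list alone, 15 members fell and 0 rose in limma-trend. Over all genes limma-trend called 0 members and limma-voom 3, TRIB3, CHAC1 and SLC7A11. With the GC and length trend removed, limma-voom no longer called CHAC1. ATF4 itself was among the 15 that fell adjusted over the list alone, at 259 ± 2.90 against 195 ± 17.8 FPKM. So were the aminoacyl-tRNA synthetase genes WARS, at 71.6 ± 3.21 against 51.9 ± 1.26, and AARS, at 121 ± 2.40 against 89.0 ± 0.526. With the preset correlation the ATF4 list was called in each of 11 alternatives, with means from -0.76 to -0.52.

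Interferon-stimulated genes, which act in antiviral defence, were higher in shNME7. Of 18 tested members 17 had a higher mean, and for 15 both shNME7 libraries lay above both shCtrl libraries. The mean log2 difference was 0.42 (SD 0.31 over members), and camera called the list with an adjusted p of 3.34e-09. That call was lost when the correlation was estimated (adjusted p = 0.469 with an estimated correlation). IFI6 stood at 22.5 ± 7.41 FPKM in shCtrl and 50.1 ± 10.6 in shNME7, and ISG15, a ubiquitin-like modifier, at 134 ± 28.2 and 277 ± 102. The rise of ISG15 was uneven, with 205 FPKM in shNME7 1 and 349 in shNME7 2. Its log2 difference was 1.01 and ran from 0.62 to 1.39 over 11 alternatives. Adjusted over the list alone, 6 members rose in limma-trend: IFI6, ISG15, IFIT1, IFIT3, RSAD2 and IFITM1. RSAD2, which encodes the antiviral protein viperin, went from 2.30 ± 0.150 to 4.51 ± 0.323 FPKM. Over all genes neither limma-trend nor limma-voom called a member. With the preset correlation the list was called in each of 11 alternatives, with means from 0.31 to 0.63.

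3 further lists were called higher by camera. Nuclear-encoded respiratory chain genes had 27 of 28 tested members with a higher mean in shNME7, 16 with both libraries above, and a mean log2 difference of 0.24 (adjusted p 1.45e-05, and adjusted p = 0.494 with an estimated correlation). In limma-trend 1 member rose adjusted over the list alone, the complex I subunit gene NDUFB8, at 4.33 ± 0.284 against 7.96 ± 0.0463 FPKM. NDUFA2, of the same complex, stood at 14.4 ± 3.13 and 27.1 ± 5.70. The split of shCtrl 2 and shNME7 1 from the other libraries gave the respiratory chain list a mean of -0.13, against 0.24 between the groups. Spread between libraries therefore stays open as a source of part of this difference. Ribosomal protein genes had 36 of 38 members with a higher mean, a mean difference of 0.19 and an adjusted p of 0.000170 (adjusted p = 0.594 with an estimated correlation). Splitting shCtrl 2 and shNME7 1 from the other libraries gave a ribosomal mean of -0.23, larger in size than between the groups, so spread between libraries can account for this difference. RPS27 stood at 450 ± 0.728 and 642 ± 62.7 FPKM. In limma-trend 0 ribosomal protein genes passed adjusted over the list alone, and the list was not called without shCtrl 2 (mean 0.08) or without shNME7 2 (mean 0.07), its adjusted p running from 7.53e-06 to 0.301 over 11 alternatives. The heat shock response had 10 of 15 members with a higher mean (mean difference 0.23, adjusted p 0.0305, and adjusted p = 0.469 with an estimated correlation). In limma-trend 2 members rose adjusted over the list alone, HSPA1A and the mitochondrial chaperonin gene HSPE1, the latter chosen after its values were seen, at 12.3 ± 0.0957 and 18.3 ± 0.689 FPKM. HSPA1A stood at 12.5 ± 0.778 and 27.3 ± 7.66 FPKM and HSPA1B at 7.05 ± 1.10 and 14.8 ± 6.77, both uncertain because they are near-identical copies. Without shCtrl 1 the heat shock list was not called (mean 0.24), and its adjusted p ran from 0.00629 to 0.121.

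Among the lists called lower, the hypoxia response had 20 of 21 tested members with a lower mean in shNME7 and 10 with both libraries below (mean log2 difference -0.25, adjusted p 1.74e-05, and adjusted p = 0.512 with an estimated correlation). Adjusted over the list alone 2 members fell, the stanniocalcin gene STC2, at 20.8 ± 2.07 against 10.3 ± 1.79 FPKM, and NDRG1, at 82.9 ± 2.21 against 45.9 ± 7.92. At the preset correlation the hypoxia list was called in each of 11 alternatives, with means from -0.35 without shNME7 1 to -0.14 without shNME7 2 and adjusted p from 6.97e-06 to 0.0431, the highest also without shNME7 2. NRF2 target genes, the antioxidant programme, had 14 of 18 members lower (mean -0.18, adjusted p 0.0144, and adjusted p = 0.469 with an estimated correlation). The 2 NRF2 list members that fell, adjusted over the list alone and in limma-voom, were FTL and SLC7A11, of which SLC7A11 also belongs to the ATF4 list. Mesenchymal and matrix genes had 10 of 15 members lower (mean -0.20, adjusted p 0.00605, and adjusted p = 0.469 with an estimated correlation). The transcription factor gene SNAI2 stood at 6.12 ± 0.163 and 3.80 ± 0.446 FPKM and VIM, the vimentin gene, at 59.4 ± 1.66 and 47.5 ± 9.34. The NRF2 list was not called without shCtrl 1 (mean -0.15) or shNME7 1 (-0.13), nor was the mesenchymal list without either (-0.14 and -0.20) or with no filter on low values (-0.12). Their adjusted p ran from 0.00216 to 0.193 and from 0.00113 to 0.245.

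Immediate early genes, which respond to growth factors, had 15 of 17 tested members with a lower mean (mean log2 difference -0.14, adjusted p 0.0305, and adjusted p = 0.494 with an estimated correlation). Replicates 2 against replicates 1 gave a mean of -0.13 for this list, about as large as between the groups. ETV5 stood at 11.95 ± 0.00792 and 7.78 ± 1.63 FPKM. Targets of YAP and TEAD had 11 of 16 lower (mean -0.13, adjusted p 0.0405, and adjusted p = 0.469 with an estimated correlation), with AJUBA at 24.2 ± 3.70 and 14.6 ± 1.46 FPKM and AMOTL2 at 9.23 ± 0.678 and 6.19 ± 0.580. In both lists 0 members passed in limma-trend adjusted over the list alone or over all genes, or in limma-voom. Gluconeogenesis and glycogen genes had 7 of 10 lower (mean -0.19, adjusted p 0.0405, and adjusted p = 0.469 with an estimated correlation), and 1 member, PPP1R3C, fell adjusted over the list alone. This glycogen-targeting phosphatase subunit gene stood at 14.9 ± 0.505 and 8.01 ± 1.57 FPKM and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase gene, at 36.1 ± 7.0 and 24.3 ± 0.306. None of these 3 lists was called without shCtrl 1, where the means were -0.07, -0.10 and -0.15, or with no filter on low values, where they were -0.11, -0.11 and -0.10. The immediate early list was also not called without shNME7 2 (-0.08), the YAP and TEAD list without shNME7 1 (-0.09), and the gluconeogenesis list without shNME7 1 (-0.20) or shNME7 2 (-0.18). Their adjusted p ran from 0.000383 to 0.353, from 0.00550 to 0.338 and from 0.0243 to 0.329 over 11 alternatives.

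**Figure D2:**
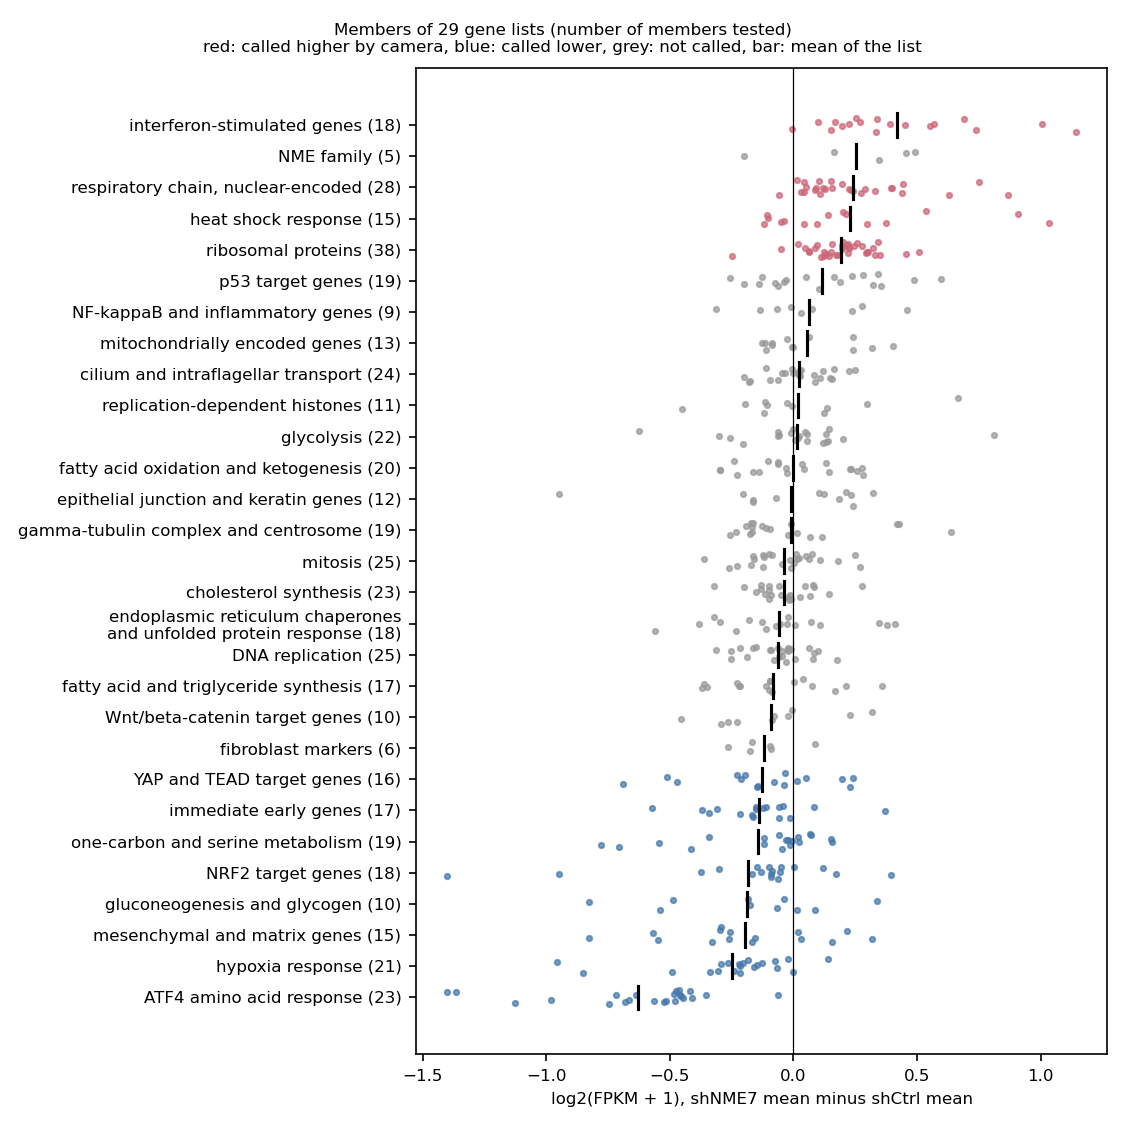
Difference in log2(FPKM + 1), shNME7 mean minus shCtrl mean, for each tested member of 29 gene lists, 1 point per gene with a bar at the list mean; red and blue mark lists that camera called higher or lower at a preset correlation of 0.01. The ATF4 list lies lowest, with a mean of -0.63, and the interferon-stimulated genes highest, with a mean of 0.42.

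Of the 29 lists 12 were called by camera, 4 higher and 8 lower, and 17 were not. With estimated correlations 0 of the 29 lists were called (smallest adjusted p 0.469). The smallest unadjusted p in that test was 0.0511, for the ATF4 list. It gave a larger p even where the estimate lay below the preset 0.01. For the heat shock list the estimate was -0.043, and camera's unadjusted p was 0.108 against 0.00898 at the preset. The lost calls therefore do not by themselves show that list members vary together. The fry test, which asks whether the members move on balance in 1 direction, called 0 (smallest adjusted p 0.266). The NME family was not called, with NME1 at 21.2 ± 0.0357 and 30.4 ± 5.52 FPKM and NME4 at 8.53 ± 1.60 and 12.1 ± 2.57. NME1 and its neighbour NME2 are similar copies, and their sum was 22.9 and 22.5 FPKM in shCtrl and 28.0 and 36.5 in shNME7. Without shNME7 1 the NME family was called higher (mean 0.42, adjusted p 0.0453, range 0.0453 to 0.550 over 11 alternatives). Gamma-tubulin complex and centrosome genes (adjusted p 0.373), cilium genes (0.733), mitosis genes (0.452) and DNA replication genes (0.173) were not called. With the GC and length trend removed the cilium list was called higher (mean 0.09, adjusted p 0.0385, range 0.0385 to 0.964), and its sign flipped in 2 of 11 alternatives, without shCtrl 1 and without shNME7 1 (mean -0.02 in each). The gamma-tubulin list flipped sign without shNME7 1 (mean 0.03). MZT2B, a gamma-tubulin complex component, stood at 25.4 ± 4.84 and 40.6 ± 11.6 FPKM, the mitotic spindle gene TPX2 at 69.3 ± 4.96 and 54.0 ± 8.19, and the ribonucleotide reductase gene RRM2 at 21.6 ± 2.09 and 17.3 ± 3.06.

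Metabolic and stress lists that were not called were fatty acid and triglyceride synthesis (adjusted p 0.118), cholesterol synthesis (0.433), fatty acid oxidation and ketogenesis (0.733), glycolysis (0.937), p53 target genes (0.135), endoplasmic reticulum chaperones (0.262) and NF-kappaB genes (0.733). Fatty acid and triglyceride synthesis was called lower in 3 of 11 alternatives, with the GC and length trend removed in limma-trend (mean -0.11, adjusted p 0.0241) and in limma-voom (-0.08, 0.0483) and without shNME7 2 (-0.15, 0.0431), over a range of 0.0241 to 0.820. LDHB, the lactate dehydrogenase B gene, had the largest difference among the glycolysis genes, at 16.8 ± 3.57 and 30.0 ± 1.02 FPKM, without passing. The chaperone-list gene HERPUD1 stood at 26.8 ± 1.05 and 17.9 ± 2.95 FPKM. Epithelial junction and keratin genes were not called (adjusted p 0.883), with a mean of -0.01 and a median of 0.11, although CLDN1 fell in limma-voom, from 7.26 ± 0.364 to 3.29 ± 0.453 FPKM. In limma-trend CLDN1 also fell adjusted over the list alone. Replication-dependent histones (0.733) and mitochondrially encoded genes (0.647) were not called and had means above and medians below 0. 1 histone gene, HIST1H3B, rose adjusted over the list alone, at 9.72 ± 0.0930 and 16.0 ± 2.03 FPKM. Over all genes it did not pass (adjusted p 0.567 in limma-trend and 0.575 in limma-voom). The mitochondrially encoded list was called higher without shCtrl 2 (mean 0.22, adjusted p 0.0473) and without shNME7 2 (0.29, 0.0169), its adjusted p otherwise reaching 0.856. Its mean changed sign, without a call, when shCtrl 1 (-0.12) or shNME7 1 (-0.18) was left out, so its direction depends on single libraries. Fibroblast markers were not called in limma-trend (mean -0.12, adjusted p 0.256) but were in limma-voom (-0.40, 0.0255). They were also called in limma-voom with the GC and length trend removed (-0.41, 0.00629), and in no other of the 11 alternatives. limma-voom filters on fragments and can include members under 1 FPKM that limma-trend did not test. The means of the 2 tests may therefore not cover the same members.

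The liver identity of the libraries was measured with 28 hepatocyte markers, and most were at or near 0 in every library. The albumin gene ALB had 1 fragment in all 4 libraries together, which allows a level of up to 0.0258 FPKM (upper end of the exact two-sided Poisson 95% interval). The genes of the apolipoproteins APOA1 and APOB and of the fibrinogen chains FGA and FGB had 0 fragments in each library, and the alpha-fetoprotein gene AFP was listed at 0 in all but shCtrl 2, where it stood at 0.0190 FPKM. The transcription factor gene HNF4A stood at 0.0682 ± 0.0235 FPKM in shCtrl and 0.0691 ± 0.0181 in shNME7. Of the 28 markers 20 had at most 3 fragments in each library, and 2 reached a mean of 1 FPKM, CEBPA at 3.29 ± 1.29 and 3.15 ± 1.31 FPKM and APOE at 1.17 ± 0.334 and 1.38 ± 0.667. Of 16 acute-phase genes 2 reached that level, C3 and C4BPA, and of 27 drug and bile acid genes 1 did, SLCO1B3. Of 21 epithelial junction and keratin genes 12 reached a mean of 1 FPKM, among them KRT18, at 178 ± 12.6 and 208 ± 37.4 FPKM, and KRT7, at 151 ± 19.5 and 164 ± 25.5. Of 13 leukocyte markers 0 reached a mean of 1 FPKM, of 11 endothelial markers 2 did, EGFL7 and CDH5, and of 13 fibroblast markers 6 did.

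**Figure D3:**
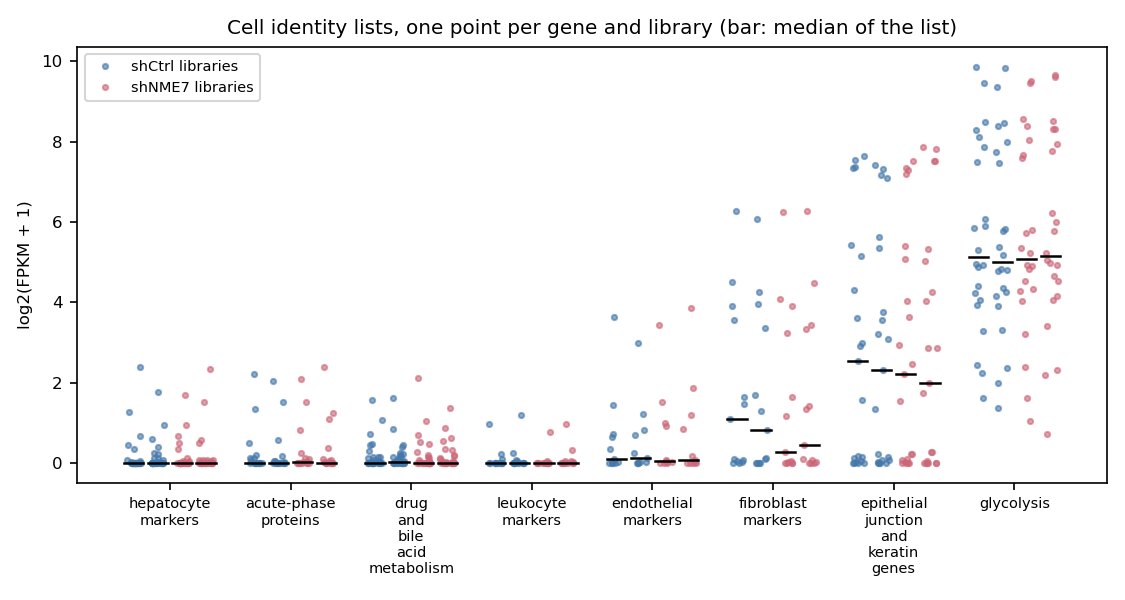
log2(FPKM + 1) of each member of 8 gene lists in each of the 4 libraries, in the order shCtrl 1, shCtrl 2, shNME7 1 and shNME7 2, with a bar at the median of the list. Hepatocyte, acute-phase, drug and bile acid and leukocyte genes lie near 0 in every library, 2 of 28 hepatocyte markers reaching a mean of 1 FPKM, whereas glycolysis genes are expressed throughout.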

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

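The alternatives with recovered fragments, GC and length removal, protein-coding genes and crossed pairing were chosen after seeing the data; the others were planned. The number of genes called, 0 in limma-trend on log2(FPKM + 1), became 122 with the replicate block, 79 of which have under 200 nt of exon; limma-voom with the block called 34 (10 higher, 24 lower). It became 104 to 650 with 1 library left out, where the lone library of a group is assumed to vary like the other group. It was 16 in limma-voom, 1 (HMGA1) with the GC and length trend removed, and 12 in limma-voom with both, of which 10 were shared with the 16. With protein-coding genes only limma-trend called 11, of which 10 were shared with limma-voom. Fewer genes were tested there, but the unadjusted p changed too. For NME7 limma-trend gave 6.19e-07 (SE 0.144) there against 0.000100 (SE 0.171) over all genes, at the same difference of -1.47. The number called in limma-trend thus depends on which genes enter the variance estimate. That number stayed 0 with a pseudocount of 0.1, with no filter and at the stricter thresholds. NME7 kept its direction in 11 of 11 alternatives. Among those with all libraries it passed with the replicate block (-1.47), in limma-voom (-2.39), in limma-voom with the trend removed (-2.24) and with protein-coding genes only (-1.47). With 1 library left out its difference ran from -1.56 to -1.38. The number of lists called, 12, was 7 with no filter on low values, 5 to 12 with 1 library left out, 0 with camera on an estimated correlation, 0 with fry and 7 with camera on ranks. It was 12 with a pseudocount of 0.1 and with protein-coding genes only, and 10 with the crossed pairing. In limma-voom it was 13, with the GC and length trend removed 13, and with both 14. With the replicate block it was 8. The one-carbon (camera adjusted p 0.0694), gluconeogenesis (0.0638), YAP and TEAD (0.0909) and immediate early (0.0665) lists were then not called. The ranges of these lists stand with each list in the report. Where none is named, the cause was not tested. The ATF4, interferon, respiratory chain and hypoxia lists were called in each of 11 alternatives of the test on genes at the preset correlation only. Same-numbered libraries deviated in opposite directions (correlation of deviations -0.35 across genes), as did their GC trends, so whether the numbers pair the samples stays open and the block is an alternative only. A crossed pairing called 0 genes in limma-trend, with 2684 at an unadjusted p under 0.05, and 1281 in limma-voom. Splitting shCtrl 2 and shNME7 1 from the other libraries gave 1451 genes at an unadjusted p under 0.05 against 859 in the real split, which points to a structure of the libraries unrelated to the groups. Its sides match the signs of the libraries' GC trends; the cause was not tested. The alternatives planned for count files (other size factors, 2 filters on counts and a negative binomial test) were not run, since the files hold FPKM. Depth limits the low genes: values under 3 fragments cannot be told from 0.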

Other observations

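In this part the tests on the hepatocyte genes and on one-carbon metabolism were chosen only after the result was seen. The 6 genes with the smallest adjusted p among those the rule had not already named were HLA-B, PAGE1, TRIM2, INHBE, ISCA1P4 and AC115618.3, and none of them passed in limma-trend. HLA-B, a gene of antigen presentation, stood at 15.6 ± 0.429 FPKM in shCtrl and 29.1 ± 0.688 in shNME7 (n = 2 each), a log2 difference of 0.85 with an adjusted p of 0.372 in limma-trend and 0.0617 in limma-voom. Reads of HLA-B can be shared with related loci. PAGE1, a cancer-testis antigen gene, stood at 10.9 ± 1.17 and 4.62 ± 0.730 FPKM, the ubiquitin ligase gene TRIM2 at 8.23 ± 0.291 and 3.80 ± 0.164, INHBE at 11.6 ± 3.01 and 3.59 ± 0.984, the processed pseudogene ISCA1P4 at 5.82 ± 0.274 and 0.497 ± 0.702, and AC115618.3, an unconfirmed transcript, at 4.18 ± 0.271 and 9.30 ± 1.01.

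The ATF4 amino acid response was lower in shNME7 as a group. A trend between libraries on GC content or gene length is argued against, since with that trend removed the mean log2 difference was -0.69. Camera's adjusted p was then 2.52e-19 at the preset correlation; without that correction the call was lost with the correlation estimated from the data (adjusted p = 0.469 with an estimated correlation) and in fry (adjusted p 0.266). The larger mean in the 2 other splits of the 4 libraries was -0.18, against -0.63. The list was taken up because it lay lowest in the real split, so smaller means in other splits are partly given. Spread unrelated to the groups therefore stays open. With 3 splits in all, no share under 0.05 can be reached; the real split called 12 lists and the highest other 3. Also open is whether the loss of NME7, an effect of the hairpin on other transcripts, or culture conditions such as medium and cell density lowered these genes. 1 hairpin label per group cannot separate them.

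Interferon-stimulated genes were higher in shNME7 as a group. With the GC and length trend removed the mean log2 difference was 0.39, which argues against that trend as the whole source. Camera's adjusted p was then 5.67e-09 at the preset correlation; without that correction the call was lost with the correlation estimated from the data (adjusted p = 0.469 with an estimated correlation) and in fry (adjusted p 0.266). The larger mean in the other splits was -0.15, against 0.42. This list was taken up because it lay highest in the real split, so the other splits cannot decide on spread unrelated to the groups. Double-stranded hairpin RNA may itself raise such genes. Both groups carry a hairpin, so a response common to any hairpin would be shared by them at equal dose. An effect of the sequence or dose of the shNME7 hairpin could not be separated from NME7 loss here. The labels do not give the sequences or doses.

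Hepatocyte genes were near 0 in all 4 libraries labelled Huh7. Too little depth is argued against by the upper limit of 0.0258 FPKM for ALB. Loss of some genes in the authors' counting or filtering is argued against, since other liver genes were low too: 6.98% of the acute-phase, drug and bile acid list members reached a mean of 1 FPKM against 84.4% of the 603 members of the lists that hold neither liver markers nor markers of other cell types. A mislabelled line and a Huh7 stock that has lost these genes cannot be told apart: 2 hepatocyte markers reached 1 FPKM in any library, which both would give, and no reference profile of Huh7 was used here. No biological explanation was tested.

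A hypothesis was that the lower one-carbon and serine metabolism list follows from its ATF4-regulated members. The 6 tested members known as ATF4 targets, MTHFD2, PSAT1 and PSPH among them, had a mean log2 difference of -0.46, and the 13 others a mean of 0.0041. The members were parted after their values had been seen, so these means describe the list and leave the hypothesis open.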
